A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

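Calling cards were read from 12 libraries of genomic DNA of Saccharomyces cerevisiae, 1 library for each of 12 groups. Per the labels, cells carried a plasmid with a factor joined to Sir4 and a plasmid with a barcoded Ty5 element that bears HIS3 and is driven by a galactose promoter. A clone was grown on galactose for 3 days, moved to rich medium for 2 days and then to plates without histidine and with 5-FOA for 3 days. DNA was cleaved in 3 digests (HinP1I, HpaII and TaqαI), circularised, and amplified outward from Ty5 by inverse PCR, again per the labels. All strains lacked SIR4. CBF1 was also deleted for Cbf1, for the 3 altered forms of Cbf1 and for both NPAS2 libraries, TYE7 for Tye7, and GCR2 for TEF1p-Tye7 gcr2D. The library with the Tye7 basic region came from BY4742 and Cbf1 bHLH-ZIP from BY4741, so in that comparison the basic region and the strain cannot be separated.

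For each library the authors supplied a list of insertions, with chromosome, position and a count of supporting reads, and a table of 4532 intergenic regions. The deposited region tables give counts of insertions (hops) in the library and in a background set, for the region itself and, in columns marked Lax, for the region widened by 200 bp on each side. TPH was read as the number of insertions per 100000 insertions of the library, BS as TPH after the background value is subtracted and floored at 0, and the deposited Log TPH as the log2 of TPH. The deposited fraction columns are shares of all insertions of the library or background, intergenic or not, and the deposited EB ratio is the fraction of the library over that of the background. The authors' Poisson p-value is the chance of more insertions than seen given the scaled background plus 0.2, and the other deposited p-value is hypergeometric. Of these meanings, those of TPH, of the Lax counts and of the Poisson p-value were checked on the values of the files. The submitters' processing notes name Novoalign for alignment. The genome build is not given in the sources used here.

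The background set held 103922 insertions, 66271 of them intergenic, for 9 libraries, and 84109 insertions, 53808 of them intergenic, for Gcr1, Gcr2 and Cst6. Each list of insertions is a series of sorted blocks, called runs, which were found from the order of chromosomes and are not named in the labels. Insertions on the list were counted again in each region, start to end inclusive, and the counts equalled those of the region tables. Depth ran from 3341 insertions for NPAS2 bHLH to 54385 for Cst6. Gene symbols came from the assembly R64, which was used for names only: of 4657 gene identifiers in the region tables, 4656 were matched. A region is named by its left and right genes, and it counts as upstream of a gene when it is the left gene on the Crick strand or the right gene on the Watson strand, by systematic name, so that a divergent region counts for both genes.

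Shares are percentages of the intergenic insertions of a library. Each of 7 comparisons applied the two-sided Fisher's exact test per region to insertions inside against outside the region, over regions with at least 10 insertions in the pair, with p adjusted by the Benjamini-Hochberg method. A region was called at an adjusted p under 0.05 and a ratio of shares of at least 2, with 1 insertion added to each count for that ratio and for log2 ratios. Printed folds are ratios of raw shares. Where 1 library held 0 insertions the fold is a lower bound computed against 3 insertions in that library, and where it held 1 to 3 the fold has its interval. Intervals are exact, Clopper-Pearson for shares and conditional on the sum of both counts for ratios, at 95%, and cover counting error only.

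A region was bound when the Poisson p-value of the authors, adjusted over all regions of a library, was under 0.01 and the region held at least 5 insertions. Bound regions were compared with 100 sets of insertions redrawn from the background. Overlaps between factors were tested by the two-sided Fisher's exact test over 4399 regions that could be bound, beside the number expected of independent lists. Spearman correlations across regions carry intervals from 1000 bootstrap draws of regions.

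The 9 gene lists were glycolysis and ethanol fermentation, sulfate assimilation and methionine, respiratory chain, phosphate regulon, phospholipid synthesis, retrograde response, galactose, ribosomal protein genes, and deletion and plasmid loci. For each list and comparison, called regions were counted with p adjusted over all regions and over the list alone, pooled insertions were tested by Fisher's exact test, and the median log2 ratio was placed among 10000 random lists of regions matched on mean share. Regions spanning a centromere were those whose left gene lies on the left arm and whose right gene lies on the right arm, 16 in all.

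The comparisons, tests, gene lists, thresholds and first set of alternatives were chosen before the data were examined. So was the rule for names: in each comparison the 10 called regions with the largest ratio each way among those with at least 20 insertions in the higher library, up to 4 members of each list with the highest shares, and the 10 bound regions with the most insertions in each library. Regions that the closing part adds were named after their values were seen.

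Alternatives recomputed each result with insertions of at least 5 reads, with positions within 5 bp merged, with no minimum of insertions, with a ratio of 4, with a pseudocount of 0.5, with the deeper library thinned, and without regions at deleted or plasmid-borne genes or within 20 kb of chromosome ends. Shares were also scaled without the 10 fullest regions of each library of the pair, called scaling outside the 10 fullest regions. Bound regions were also called at an adjusted p under 0.0001, with the hypergeometric p-value, with at least 10 insertions and after thinning to the shallowest library. Lists were recomputed with regions upstream of 1 gene only and without the fullest member. Those chosen after the data were seen are named in the closing part on processing.

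The region test was tested on simulated data drawn at the depth of each pair. Ratios of 2, 4 and 8 were put into known regions by raising their insertions in 1 library, and 0 regions were called in the wrong direction. Of regions left unchanged, 4 of 612 were called for Tye7 against Cbf1, 3 of 264 for Cbf1 bHLH-ZIP against Cbf1, 1 of 676 for removal of the ZIP, 1 of 131 for the basic region, 1 of 41 for the ZIP added to NPAS2, 5 of 157 for loss of GCR2 and 4 of 337 for the TEF1 promoter. These draws held counting error only, with no spread between runs. Set between the 2 fullest runs of a library, the same test called 13 of 132 regions in Gcr1 and 17 of 390 in Gcr2. It called 4 of 87 in the basic-region library, 6 of 373 in Cst6 and 1 of 41 in TEF1p-Tye7. In Cbf1 bHLH-ZIP it called 1 of 109 and in Cbf1 bHLH 1 of 652. In Cbf1, Tye7 and TEF1p-Tye7 gcr2D it called 0. Shares of CACGTG sites near insertions, and distances to centromeres, were planned but not analysed here, because the analysis used no sequence or feature positions matched to the build of the files. The widened (Lax) columns were not used here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.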

Results

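Insertions of a Ty5 retrotransposon were mapped in Saccharomyces cerevisiae cells that expressed a transcription factor, or a part of one, fused to Sir4, the protein that steers Ty5 to chromatin. Insertions gather near positions where the fusion binds, beside others that it does not direct, and the share of a library's intergenic insertions that falls in a region measures how often the region was used. The 12 libraries fell into 12 groups of 1 library each. They covered the full-length factors Cbf1, Tye7, Gcr1, Gcr2 and Cst6, 3 shortened or altered forms of Cbf1, the mammalian circadian factor NPAS2 reduced to its basic helix-loop-helix (bHLH) domain with or without the leucine zipper (ZIP) of Cbf1, and Tye7 driven by the TEF1 promoter in cells with or without GCR2. Differences between libraries therefore have no replicate check, and every test compares 1 library with another, not 1 condition with another. Percentages and ratios carry exact 95% intervals that cover counting error only.

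The full-length libraries held 34773 insertions for Cbf1, 24003 for Tye7, 23460 for Gcr1, 33197 for Gcr2 and 54385 for Cst6. The library of NPAS2 bHLH held 3341 insertions and that of NPAS2 bHLH with the Cbf1 ZIP held 4623. TEF1p-Tye7 reached 11455 insertions with GCR2 and 12288 without it (gcr2D). The Cbf1 bHLH-ZIP library held 10350 insertions, its version with the basic region of Tye7 held 9315, and the Cbf1 bHLH library, which lacks the ZIP, held 34942. Between 61.8% and 78.1% of a library's insertions lay in the 4532 intergenic regions listed. The lists of insertions were built from 1 to 6 joined blocks, called runs here, which the labels do not name. Runs show the spread inside a library and were not used as replicates.

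Genes deleted or carried on plasmids were read first, because insertions inside a deleted gene would contradict a label. Cells of the Cbf1 and NPAS2 libraries lacked CBF1 by label, and the libraries of Cbf1, Cbf1 bHLH-ZIP and Cbf1 bHLH held 2, 0 and 0 insertions within CBF1. The TEF1p-Tye7 gcr2D library held 0 insertions within GCR2, and TEF1p-Tye7, where GCR2 was present, also held 0. SIR4, deleted in every strain, held 1 insertion in the Gcr1 library, 1 in the Cbf1 bHLH library and 0 in each of the other 10 libraries. These deleted genes took so few insertions that the counts checked no label. GCR1 held 16 insertions in the Gcr1 library, 10 in Gcr2 and 6 in TEF1p-Tye7, and 0 or 1 in each other library. GCR2 held 6 in the Gcr2 library. Whether any of these insertions lay in a plasmid copy was not tested.

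A region was called bound when the authors' Poisson p-value, adjusted over regions, was under 0.01 and it held at least 5 insertions. Cbf1 had 177 bound regions, Cst6 162, Cbf1 bHLH 99, Cbf1 bHLH-ZIP 93, Gcr2 79, Cbf1 bHLH-ZIP with the Tye7 basic region 76, Gcr1 64, NPAS2 bHLH with the Cbf1 ZIP 47, TEF1p-Tye7 gcr2D 44, TEF1p-Tye7 25, Tye7 17 and NPAS2 bHLH 1. Most of these numbers depend on depth: thinned to the shallowest library, Cbf1 kept 64, Cst6 54, Cbf1 bHLH-ZIP 51, the basic-region library 43, Gcr1 38, Gcr2 26, TEF1p-Tye7 gcr2D 18 and Cbf1 bHLH 11. Insertions redrawn 100 times from the deposited background gave a mean of 17.9 bound regions for Cst6, 3.08 for Gcr2 and 1.54 for Cbf1. The Cbf1 library was led by IDH1-NCE103, upstream of a subunit of isocitrate dehydrogenase and of carbonic anhydrase, with 4.05% of its insertions. It was followed by MET5-IML1 with 3.05% and CAF120-MET2 with 3.04%, both next to genes of methionine synthesis, and by GNP1-SMT3 with 2.53%. Cst6 had its largest shares at SCM4-YGR054W (3.74%), at ACC1-TIM23 (3.58%), which serves acetyl-CoA carboxylase and a mitochondrial import channel, and at COT1-FAA1 (3.46%).

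The comparison of Tye7 with Cbf1 asked where these bHLH factors, which share a preference for the E-box sequence CACGTG, bind different promoters. PFK2-HFA1, upstream of a phosphofructokinase subunit (chromosome 13, 674765 to 677192), held 1.38% of the Tye7 insertions against 1 insertion of Cbf1, a ratio of 375 with an interval of 66.6 to 14873 (exact test, adjusted p 2.86e-92). TDH3-PDX1, upstream of a glyceraldehyde-3-phosphate dehydrogenase, held 3.38% against 0.0184%. FBA1-MPE1, upstream of aldolase, held 80 insertions of Tye7 and 0 of Cbf1, at least 45.2-fold higher, and TPI1-DBF4, upstream of triose phosphate isomerase, held 20 and 0, at least 11.3-fold higher. SPC97-ENO2 held 0.881% of Tye7 insertions and 3 insertions of Cbf1, a ratio of 79.7 (26.7 to 391). PGI1-TAF5 was 56.9-fold higher, PDC1-STU2 43.1-fold, ADH1-PHM7 30.6-fold, GPI2-GCR1 18.9-fold and VHR1-GPP1, upstream of a glycerol phosphatase gene, 17.7-fold.

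In the other direction, LPD1-SMX2, upstream of dihydrolipoamide dehydrogenase (chromosome 6, 103121 to 103693), held 1.43% of the Cbf1 insertions and 1 insertion of Tye7, which put Tye7 lower by a factor of 228 (40.7 to 9034; exact test, adjusted p 8.28e-75). PSR1-COX17 held 1.36% against 1 insertion (lower by a factor of 218, interval 38.8 to 8615) and ATP7-PUT3 held 1.70% against 2 insertions (136, 37.4 to 1125). PTR3-MET10, upstream of a sulfite reductase subunit, held 0.969% against 1 insertion (155, 27.6 to 6147). MET5-IML1 was 97.5-fold lower in Tye7, CAF120-MET2 81.1-fold and IDH1-NCE103 81.0-fold. Tye7 had 0 insertions in YDJ1-MTQ1, GPI19-THI74 and MET18-STH1, where Cbf1 had 160, 140 and 123, so these were at least 31.4-fold, 27.5-fold and 24.2-fold lower.

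**Figure D1:**
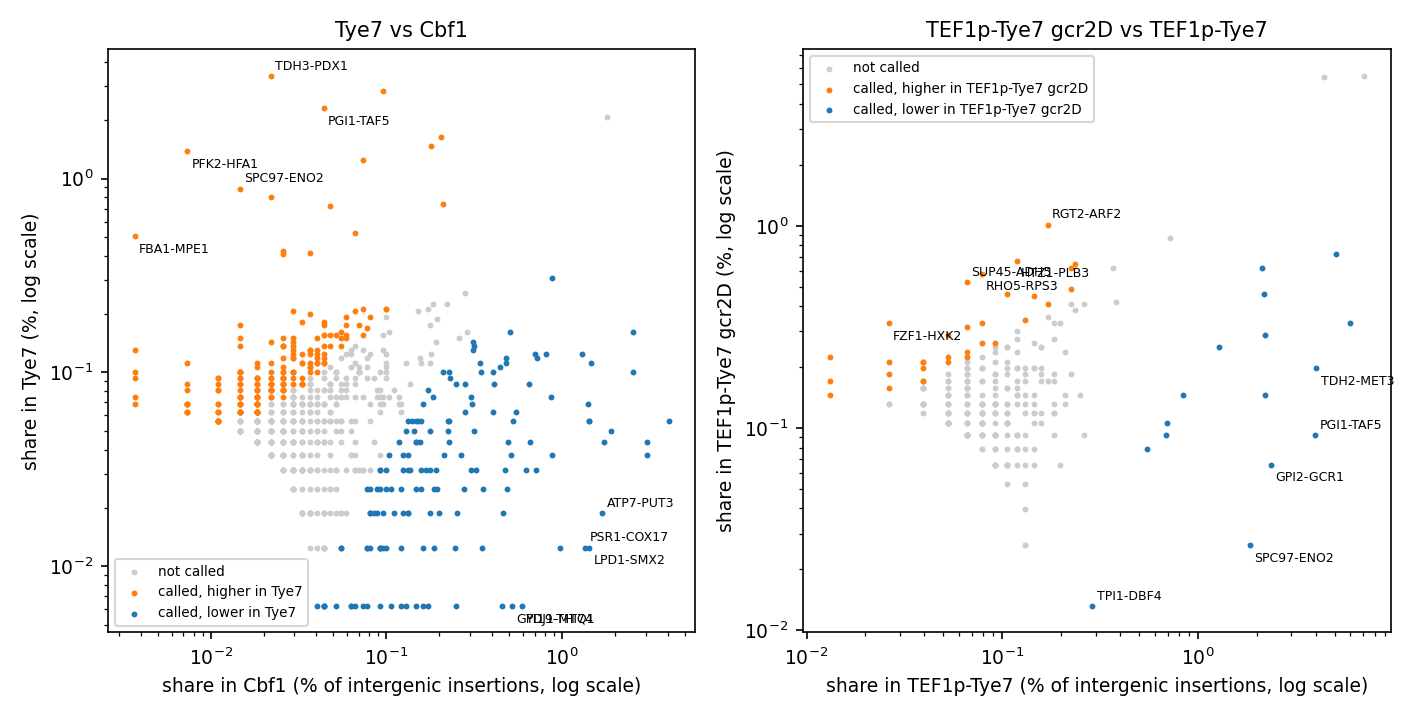
Share of intergenic insertions (%, both axes logarithmic, 1 insertion added) in Tye7 against Cbf1 and in TEF1p-Tye7 gcr2D against TEF1p-Tye7, each point 1 region tested. TDH3-PDX1 held 3.38% in Tye7 and 0.0184% in Cbf1, and SPC97-ENO2 held 1.84% in TEF1p-Tye7 and 1 insertion in the gcr2D library, whereas the number of orange points on the left depends on the scaling, 205 or 31.

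Of 759 regions with at least 10 insertions in the pair, 205 were higher in Tye7 and 151 lower by the two-sided Fisher's exact test with an adjusted p under 0.05 and a ratio of at least 2. With shares scaled on regions bound in neither library the split was 31 higher and 225 lower, 12.1% higher in place of 57.6%, and the log2 ratios moved by -1.17. With scaling outside the 10 fullest regions they moved by -0.11. All 10 named higher and all 10 named lower regions passed under both scalings, and 189 of the 205 higher regions were bound in neither library. Requiring every run of Tye7 to lie on 1 side of every run of Cbf1 left 68 higher and 115 lower regions. Merging positions within 5 bp left 27 and 91 and insertions of at least 5 reads 134 and 120, with all named regions except VHR1-GPP1 and IDH1-NCE103 kept by merging and all kept by the read minimum.

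Among the gene lists, the glycolysis and ethanol fermentation regions took 18.6% of Tye7 insertions (18.0 to 19.3) and 3.42% of Cbf1 insertions (3.21 to 3.65). Of its 20 regions, 13 were higher and 1 lower, with 13 and 1 also when adjusted over the list alone, and its median log2 ratio of 3.45 lay at percentile 100 of 10000 random matched lists. TDH2-MET3, shared by a glycolytic and a sulfate assimilation gene, was used by both factors, with 2.08% in Tye7 and 1.79% in Cbf1. The sulfate assimilation and methionine list took 3.16% of Tye7 and 16.2% of Cbf1 insertions, with 1 region higher and 19 lower, the same adjusted over the list alone, at percentile 0. Its lower regions included MET6-IES5, upstream of methionine synthase, 22.5-fold lower in Tye7.

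The other lists gave mixed results in the same pair. The phosphate regulon list took 3.19% and 3.05%, with 2 regions higher, ADH1-PHM7 among them, and 5 lower, such as PHO84-GTR1, 28.5-fold lower. Its pooled log2 ratio of 0.07 turned to -0.04 with scaling outside the 10 fullest regions and to -1.11 with scaling on regions bound in neither library. Without the fullest member of the list it was -2.96, and with regions upstream of 1 gene only it was -2.88. Respiratory chain regions took 0.806% and 4.31%, with 3 higher and 6 lower, and their median log2 ratio of 0.76 had the opposite sign to the pooled ratio of 0.187. The retrograde response list likewise had a median of 0.39 beside a pooled ratio of 0.112, with 1 region higher and 4 lower, IDH1-NCE103 carrying most of its Cbf1 insertions. The phospholipid synthesis list, 0.394% against 0.199% with 0 regions called either way, and the ribosomal protein list, 3.59% against 2.26% with 12 higher and 5 lower (13 and 5 adjusted over the list alone), turned to pooled log2 ratios of -0.19 and -0.51 with scaling on regions bound in neither library. The galactose list took 0.487% and 0.162% with 4 regions higher, GAL7-GAL10 and RIO1-GCY1 among them, of which 0 had runs apart. Deletion and plasmid loci took 0.906% and 1.88%, with GPI2-GCR1 higher, 3 regions lower and a median log2 ratio of 1.18 opposite to the pooled ratio of 0.481. Counts of these lists for which a single pair is given were the same adjusted over the list alone. Their medians lay at percentile 2.59 for phosphate, 1.94 for the respiratory chain, 11.95 for the retrograde response, 38.8 for phospholipids, 98.1 for galactose, 61.0 for deletion and plasmid loci and 99.6 for ribosomal proteins.

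**Figure D2:**
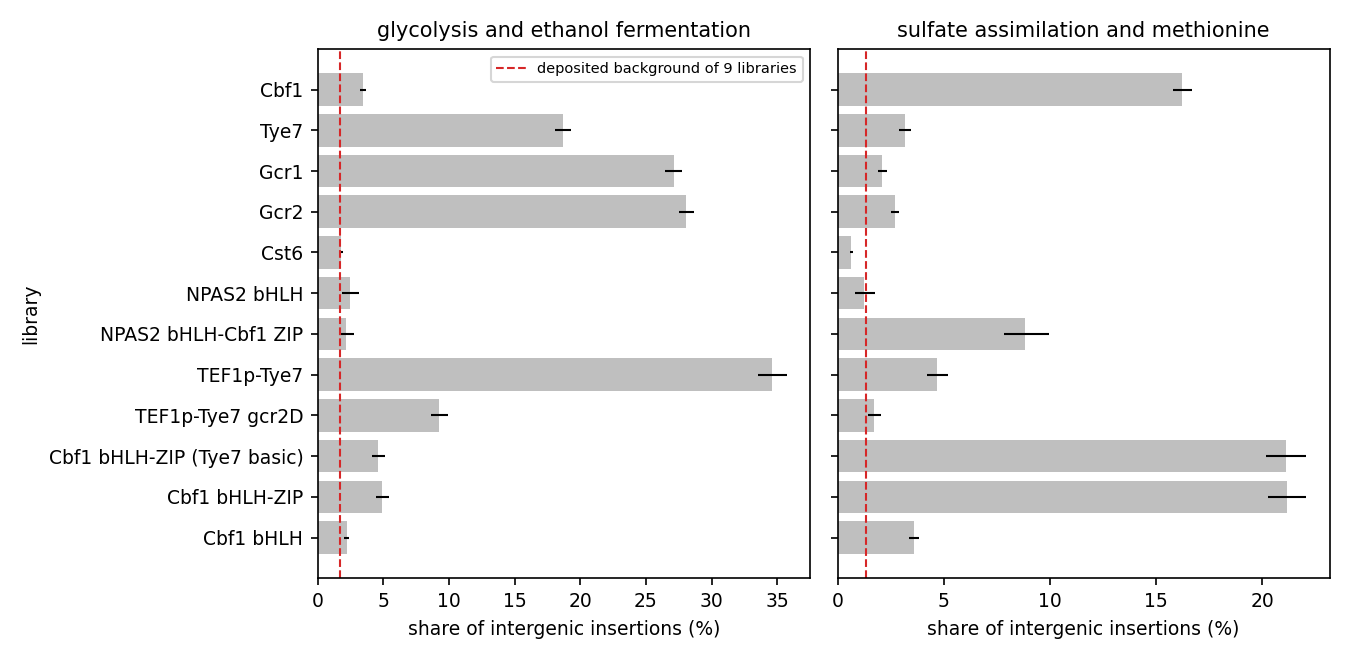
Share of intergenic insertions (%) in the regions of the glycolysis and of the sulfate assimilation list for each of the 12 libraries, as bars with exact 95% intervals, the dashed line giving the background deposited for 9 of them (1.68% and 1.32%). Glycolytic shares ran from 1.75% in Cst6 to 34.6% in TEF1p-Tye7, and sulfate shares from 0.654% in Cst6 to 21.2% in Cbf1 bHLH-ZIP.

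The 5 full-length factors were compared to ask which promoters several of them used together. Gcr1 and Gcr2, the glycolysis regulators, put 27.1% and 28.1% of their insertions into the glycolysis list, where their background held 1.84%. They shared 51 bound regions where independent lists of these sizes would share 1.15 (two-sided Fisher's exact p 7.34e-86). All 17 regions bound by Tye7 were also bound by Gcr2, and 16 of them by Gcr1. The 16 regions bound by Tye7, Gcr1 and Gcr2 included 13 of the glycolysis list, such as TDH3-PDX1, PGI1-TAF5, PFK2-HFA1 and PUP2-ENO1. The other 3 were ECM32-BMH1, upstream of a 14-3-3 protein, VHR1-GPP1 and GPI2-GCR1, upstream of GCR1 itself. The last is among the deletion and plasmid loci, and insertions in a plasmid copy were not told apart. Gcr1 also used MNT2-ADH4, upstream of an alcohol dehydrogenase, with 4.41% of its insertions.

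Cst6 and Cbf1 shared regions with this group as well. Cst6 shared 12 bound regions with Gcr2 (2.91 by independence, exact p 2.49e-05) and 11 with Gcr1 (2.36, exact p 1.65e-05), and Cbf1 shared 9 with Gcr2 (3.18, exact p 0.00409) and 7 with Gcr1 (2.58, exact p 0.0136). Insertions redrawn from the background shared a mean of 0.5 and at most 4 regions for Cst6 with Gcr2. For Cst6 with Gcr1 the values were 0.11 and 1, and for Cbf1 with either 0. The exact test takes all regions as equally likely to be bound. With bound regions called at an adjusted p under 0.0001, the overlaps with Gcr2 fell to 7 for Cst6 and 5 for Cbf1. Cst6 shared 3 bound regions with Tye7 (0.626 by independence, exact p 0.0228), namely ADH1-PHM7, VHR1-GPP1 and MAM3-GPD2. Cbf1 shared 3 with Tye7 (0.684, exact p 0.0287), namely PEP8-TDH1, TDH2-MET3 and ECM32-BMH1, and 20 with Cst6 (6.52, exact p 5.48e-06). Over the 5 factors, 312 regions were bound by 1, 50 by 2, 21 by 3, 6 by 4 and 0 by all 5. The regions bound by 4 were PEP8-TDH1, TDH2-MET3, ADH1-PHM7, TRS23-VHS1, ECM32-BMH1 and VHR1-GPP1. Rank correlations across regions, which are not independent replicates, were 0.658 for Gcr1 with Gcr2, 0.529 for Tye7 with Gcr2 and 0.361 for Tye7 with Gcr1, against -0.0722 for Tye7 with Cbf1 (interval -0.148 to 0.00137). Over the same regions the background correlated with Tye7 at 0.682 and with Gcr2 at 0.629 for their pair, with Tye7 at 0.668 and Gcr1 at 0.406, and with Gcr1 at 0.446 and Gcr2 at 0.608, so the Tye7 correlations were no larger than those with the background. ADH1-PHM7 held 0.0260% to 3.89% of a Gcr1 run, so its Gcr1 and Gcr2 values depend on the runs included. With only runs 3 and 4 of Gcr1 and run 1 of Gcr2 the shared bound regions numbered 29 in place of 51. In those runs Gcr1 had 46 bound regions in place of 64 and Gcr2 59 in place of 79. The fall in shared regions can therefore not be separated from the loss of depth.

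**Figure D3:**
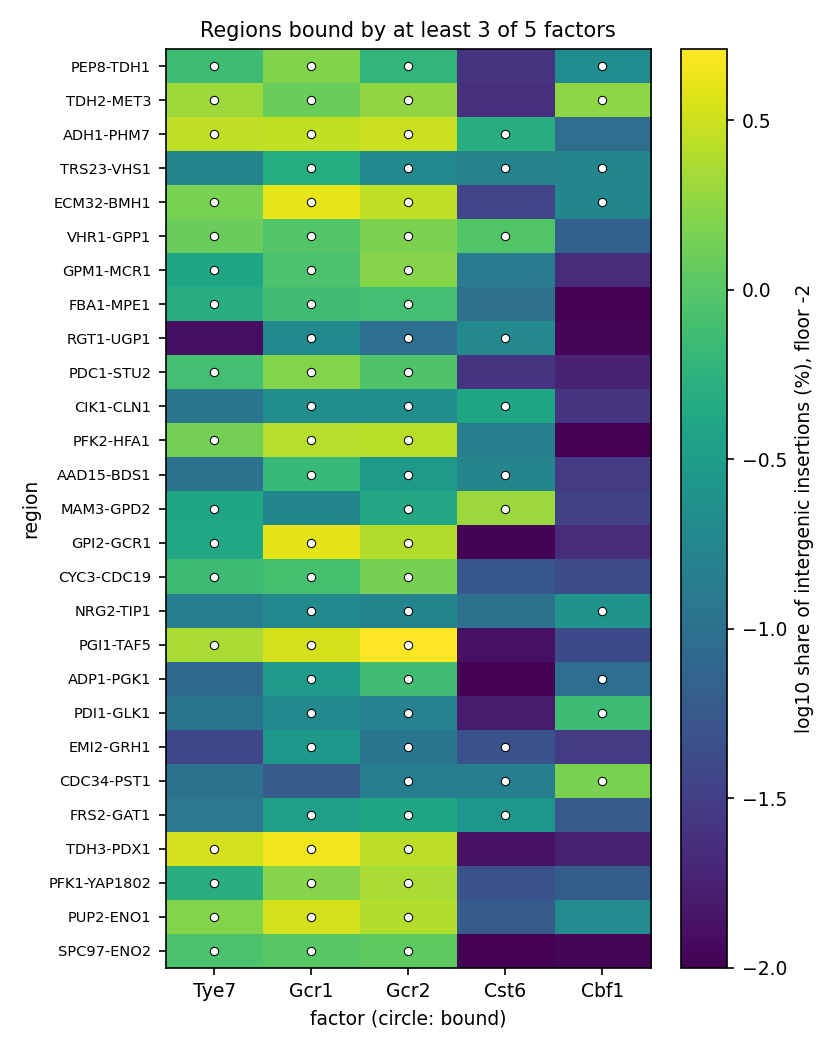
Regions bound by at least 3 of the 5 full-length factors (vertical axis) by factor (horizontal axis), coloured by the log10 of the share of intergenic insertions (%), with a circle where bound. Of the 27 regions drawn, 16 carry circles for Tye7, Gcr1 and Gcr2, and PGI1-TAF5 has the largest value, 5.13% in Gcr2.

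TEF1p-Tye7 was set against Tye7 to ask what the foreign promoter changed, although by label only the Tye7 strain also lacked TYE7. MNT2-ADH4 held 7.03% of TEF1p-Tye7 insertions and 0.169% of Tye7 insertions, 41.7-fold higher (28.3 to 63.8; exact test, adjusted p 3.27e-225). PEP8-TDH1 was 6.0-fold higher, GPI2-GCR1 5.59-fold, PDI1-GLK1, upstream of glucokinase, 3.27-fold, PUP2-ENO1 3.12-fold, PDC1-STU2 2.67-fold, FBA1-MPE1 2.52-fold and SPC97-ENO2 2.09-fold. KAE1-GAP1, upstream of the general amino acid permease, held 1 insertion against 28 and was lower by a factor of 13.3 (2.20 to 544). ADH1-PHM7 was lower by a factor of 4.13, but it held 1.61% in run 2 of TEF1p-Tye7 and 0.182% in the other runs, and with run 2 alone the number of lower regions was 0. Run 2 held 2670 of the 7609 intergenic insertions of TEF1p-Tye7.

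In all, 9 regions were higher and 3 lower of 457 tested, and all 17 regions bound in Tye7 were bound in TEF1p-Tye7. Scaling outside the 10 fullest regions gave 22 and 1 (a log2 shift of 0.53) and scaling on regions bound in neither gave 28 and 1 (0.63), or 95.7% and 96.6% higher in place of 75.0%. ADH1-PHM7 and KAE1-GAP1 together kept 1 call of 2 under either scaling. Merging positions within 5 bp gave 14 higher and 0 lower, kept 6 of the 8 named higher regions and turned the log2 ratio of ADH1-PHM7 from -2.02 to 0.31. The glycolysis list took 34.6% against 18.6%, with 6 regions higher and 1 lower, or 8 and 1 adjusted over the list alone, and its median log2 ratio of 0.81 was at percentile 100. The sulfate list took 4.69% against 3.16% with 0 regions called, either adjusted over the list alone or over all regions. Its median log2 ratio of -0.38 (percentile 16.7) was opposite in sign to the pooled ratio of 1.48, and without TDH2-MET3 the pooled log2 ratio was -0.67.

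Loss of GCR2 was examined in the TEF1p-Tye7 background, to ask whether Tye7 needs Gcr2 at glycolytic promoters. SPC97-ENO2 (chromosome 8, 450806 to 451327) held 1.84% with GCR2 and 1 insertion without it, lower by a factor of 140 (24.7 to 5556; exact test, adjusted p 2.46e-39). PGI1-TAF5 was lower by a factor of 50.2 (22.8 to 138), GPI2-GCR1 by 44.4, TDH2-MET3 by 21.8, TDH3-PDX1 by 19.0, ECM32-BMH1 by 16.7, PFK1-YAP1802 by 8.48, PFK2-HFA1 by 7.89 and PUP2-ENO1 by 7.15. TPI1-DBF4 held 21 insertions with GCR2 and 0 without, at least 6.98-fold lower. The largest regions of the gcr2D library were not called, since their ratios were under 2: PEP8-TDH1 held 4.39% with GCR2 and 5.44% without (exact test, adjusted p 0.0209), and MNT2-ADH4 held 7.03% and 5.51% (adjusted p 0.00122). The log2 ratio of PEP8-TDH1, 0.31, turned to -0.22 with scaling outside the 10 fullest regions and to -0.30 on regions bound in neither, and that of MNT2-ADH4, -0.35, moved to -0.88 and -0.96.

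Among regions higher without GCR2, FZF1-HXK2, upstream of hexokinase 2, held 24 insertions against 1, a ratio of 24.1 (3.92 to 989; exact test, adjusted p 1.04e-05). SUP45-ADH5 was 9.77-fold higher, RHO5-RPS3 8.62-fold, RGT2-ARF2 6.35-fold and HTZ1-PLB3 6.26-fold. IML3-CMD1 held 21 insertions against 3, a ratio of 7.02 (2.09 to 36.7), with overlapping runs. STP4-SIT4 was 5.76-fold higher, ADH4-ZRT1, upstream of a zinc transporter, 4.87-fold, BIO2-IMA1 4.81-fold and SEC7-HSP42, upstream of a small heat shock protein, 3.31-fold.

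Of 270 regions tested, 32 were higher without GCR2 and 16 lower. Scaling outside the 10 fullest regions gave 11 and 20 (35.5% higher in place of 66.7%, log2 shift -0.53), and scaling on regions bound in neither gave 9 and 20 (31.0%, shift -0.61). The 10 named lower regions passed under both scalings, whereas 8 and 6 of the 10 named higher regions did, and with run 2 of TEF1p-Tye7 alone 9 regions were higher. With that run alone 182 regions could be tested in place of 270. Merging positions within 5 bp left 0 higher and 12 lower regions, with 0 of the 10 named higher regions kept and all named lower regions except TDH2-MET3 and TDH3-PDX1, and no minimum of insertions gave 15 and 16. The glycolysis list took 9.26% of insertions without GCR2 (8.62 to 9.94) and 34.6% with it (33.6 to 35.7), with 1 region, FZF1-HXK2, higher and 13 lower, or 1 and 14 adjusted over the list alone. Its median log2 ratio of -2.63 was at percentile 0 of the random lists. The sulfate list fell from 4.69% to 1.73% with 1 region higher, EXG1-MET17, and 1 lower, or 2 and 1 adjusted over the list alone, and its median log2 ratio of 1.00 (percentile 66.9) had the opposite sign. Without TDH2-MET3, which held 4.02% with GCR2 and 0.184% without, the pooled log2 ratio of the list was 1.19.

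Cbf1 bHLH-ZIP was set against Cbf1 to ask how far the DNA-binding and dimerisation domains alone account for the places Cbf1 used. All 93 regions bound by Cbf1 bHLH-ZIP were among the 177 of Cbf1. LAC1-CAP1, upstream of a ceramide synthase (chromosome 11, 428194 to 428945), held 4.15% against 1.89%, a ratio of 2.19 (1.91 to 2.52; exact test, adjusted p 4.93e-25). XDJ1-SUL2, upstream of a sulfate permease, was 2.18-fold higher, MET6-IES5 2.11-fold, SYG1-MET30 2.01-fold and MET18-STH1 2.01-fold. CSM1-ABP1 held 0 insertions against 27, at least 2.66-fold lower. SFB3-TRA1 held 2 insertions against 42 (lower by a factor of 6.21, 1.62 to 53.0) and COG6-BDP1 held 3 against 47 (4.63, 1.49 to 23.3). PRM5-HIS5 was lower by a factor of 4.44, SET2-ERG20 by 4.38, KTI12-HAP4 by 3.96 and MAK21-LCB2 by 2.99.

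In total 6 regions were higher and 7 lower of 428 tested. The scaling outside the 10 fullest regions gave 8 and 1, or 88.9% higher in place of 46.2% (log2 shift 0.20), and kept 1 of the 7 lower regions. Scaling on regions bound in neither gave 12 and 0, or 100% higher (shift 0.37), and kept none of the 7. With positions within 5 bp merged, the counts were 14 and 0, which also kept none, and with insertions of at least 5 reads or no minimum 1 of the 7 was kept. The sulfate list took 21.2% and 16.2%, with 3 regions higher and 0 lower, the same adjusted over the list alone, a median log2 ratio of -0.07 opposite in sign to the pooled ratio of 1.30, and percentile 21.0. MET5-IML1 and CAF120-MET2 were not called, with 2.72% against 3.05% and 3.82% against 3.04%. Glycolysis regions took 4.90% and 3.42% with 0 called by either adjustment, at percentile 37.4.

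Removal of the ZIP, a coiled coil with which Cbf1 dimerises, was examined by setting Cbf1 bHLH against Cbf1 bHLH-ZIP. Without the ZIP the sulfate and phosphate lists, given below, took smaller shares, as did the lists of glycolysis (2.20% against 4.90%), the respiratory chain (1.65% against 4.35%), the retrograde response (0.915% against 4.29%) and deletion and plasmid loci (0.428% against 2.39%). Called regions were evenly split for glycolysis (3 higher and 3 lower, or 6 and 4 adjusted over the list alone) and the respiratory chain (2 and 2, or 2 and 3). The lists of phospholipid synthesis (0.506% against 0.162%, exact test, adjusted p 7.5e-06) and galactose (0.463% against 0.125%, adjusted p 3.91e-06) took larger shares with 0 regions called by either adjustment, and their pooled log2 ratios of 1.55 and 1.77 moved to 0.03 and 0.25 on regions bound in neither (adjusted exact p 0.888 and 0.621). The pooled log2 ratios of glycolysis and the respiratory chain, -1.16 and -1.40, turned to 0.72 and 0.65 with regions upstream of 1 gene only, and the median log2 ratios of glycolysis (0.61) and the retrograde response (0.63) were opposite in sign to the pooled ones. PTR3-MET10 (chromosome 6, 212961 to 213300) held 0.0273% against 1.28%, lower by a factor of 47.1 (22.0 to 120; exact test, adjusted p 1.94e-53). GPI19-THI74 held 1 insertion against 21 (lower by a factor of 67.2, 10.8 to 2779) and VTC3-CTF19, upstream of a polyphosphate polymerase subunit, held 2 against 23 (36.8, 9.09 to 322). LPD1-SMX2 was lower by a factor of 29.1, NDI1-NGL3, upstream of the internal NADH dehydrogenase, by 21.8, VTC4-RPC17 by 20.8, LAC1-CAP1 by 19.0, MET5-IML1 by 17.4, ACS1-FLC2 by 15.4 and CAF120-MET2 by 14. The 10 fullest regions took 4.56% of the insertions of Cbf1 bHLH and 33.6% of those of Cbf1 bHLH-ZIP. Still, 49 regions were bound in both.

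The 10 named regions with larger shares without the ZIP all held 0 insertions in Cbf1 bHLH-ZIP. CWP2-CWP1, next to a pair of cell wall mannoprotein genes, held 49 insertions in Cbf1 bHLH (at least 5.10-fold higher), GSP2-TUF1 38 (at least 3.96-fold), JJJ2-HSP150 35, YPR148C-NCE102 35, NDL1-HAP1 34, RAD2-TNA1 34, MSC6-GDS1 33, FLO9-GDH3 31, PEX25-CAR1 30 and CIK1-CLN1 29 (at least 3.02-fold). Of 807 regions tested, 70 were higher and 57 lower. Scaling outside the 10 fullest regions gave 8 and 82 (8.89% higher in place of 55.1%, log2 shift -0.63), and scaling on regions bound in neither gave 0 and 134 (0% higher, shift -1.52), so that 7 and 0 of the 10 named higher regions and all 10 named lower regions passed. Merging positions within 5 bp left 1 higher and 73 lower regions, and insertions of at least 5 reads left 3 and 42, each with 1 of the 10 named higher regions. No minimum of insertions left 19 and 51.

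Without run 3 of Cbf1 bHLH, 25 regions were higher in place of 70, among them 2 of the 10 named. Run 3 held 20443 of the 25688 intergenic insertions, and without it 216 regions could be tested in place of 807. The fall can therefore not be separated from the loss of depth. The sulfate list took 3.58% of Cbf1 bHLH insertions (3.35 to 3.81) and 21.2% of those of Cbf1 bHLH-ZIP (20.3 to 22.1), with 1 region higher and 14 lower, or 2 and 16 adjusted over the list alone, at percentile 0. The phosphate regulon list took 0.849% against 2.38%, with PHO84-GTR1, SPL2-ARO9, VTC4-RPC17 and VTC3-CTF19 lower and 0 higher, or 4 and 1 adjusted over the list alone, at percentile 0.04. Ribosomal protein regions took 4.4% against 1.86%, a pooled log2 ratio of 1.24 that turned to -0.28 with scaling on regions bound in neither, and 2 regions were higher and 1 lower (0 and 1 adjusted over the list alone), at percentile 98.5.

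The same ZIP was added to NPAS2 bHLH to ask whether it changes the places used by a foreign bHLH domain. ATG41-RPL36B, upstream of an autophagy gene (chromosome 16, 74719 to 75699), held 19.5% with the ZIP (18.0 to 21.0) and 0.373% without it, 52.3-fold higher (27.3 to 115; exact test, adjusted p 1.92e-142). SYG1-MET30, upstream of a ubiquitin ligase subunit that controls sulfur genes, held 120 insertions and 0, at least 33.8-fold higher. TAH1-BUD31 held 116 and 1 (98.0, 17.2 to 3903) and PDR8-SEC22 held 114 and 2 (48.1, 13.0 to 402). NDI1-NGL3, GUT2-IMP21 and CLN2-BBP1 held 39, 30 and 26 insertions with the ZIP and 0 without, at least 11-fold, 8.45-fold and 7.32-fold higher. VTC3-CTF19 held 52 and 2 (22.0, 5.78 to 186) and LPD1-SMX2 48 and 2 (20.3, 5.31 to 172). RRM3-PIH1, next to a DNA helicase gene, was 21.5-fold higher, and CIS3-FAR1, the only region bound by NPAS2 bHLH, held 9.20% against 0.911%.

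Of 62 regions tested, 37 were higher with the ZIP and 3 lower, and 36 of the 37 were bound. Scaling outside the 10 fullest regions gave 46 and 1 (log2 shift 1.10) and scaling on regions bound in neither 51 and 0 (shift 2.09), with all 10 named regions kept. With insertions of at least 5 reads, 17 regions could be tested, and 12 were higher, 6 of the 10 named among them, and 0 lower. The sulfate list took 8.85% (7.83 to 9.95) against 1.24%, with 7 regions higher and 0 lower, the same adjusted over the list alone, GTO1-CYS4 and SCS3-MET13 among them, at percentile 99.7. Glycolysis regions took 2.13% and 2.44%, a pooled log2 ratio of -0.20 that turned to 0.90 outside the 10 fullest regions and to 1.89 on regions bound in neither. PEP8-TDH1 and TDH2-MET3 were higher and ADH1-PHM7 lower, the same adjusted over the list alone, at percentile 12.3.

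**Figure D4:**
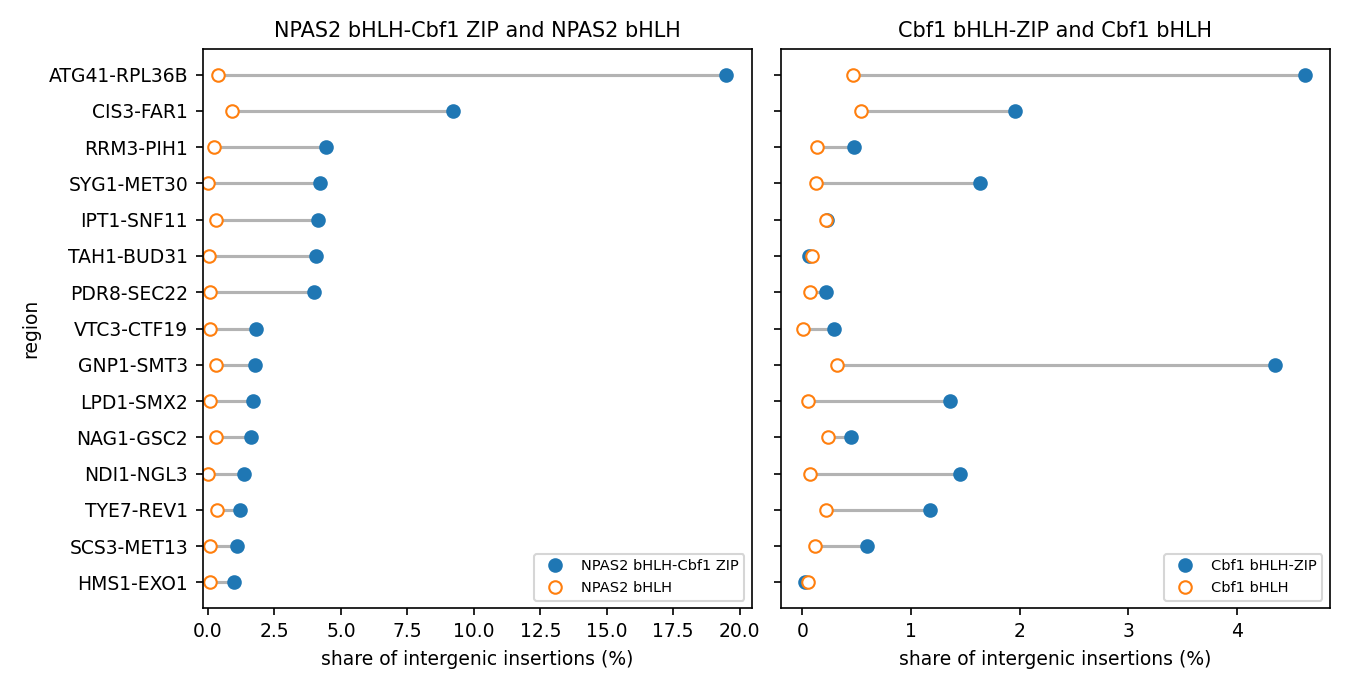
Share of intergenic insertions (%, horizontal axis) with the ZIP (filled) and without it (open) for NPAS2 and for Cbf1, in the 15 regions with the most NPAS2 insertions among those higher with the ZIP. ATG41-RPL36B went from 0.373% to 19.5% in NPAS2 and from 0.463% to 4.62% in Cbf1. TAH1-BUD31 was not called in Cbf1, with 5 of 8028 insertions in Cbf1 bHLH-ZIP and 23 of 25688 in Cbf1 bHLH (log2 ratio -0.32).

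Among 59 regions tested in both pairs, 17 were higher with the ZIP in Cbf1 and 34 in NPAS2, 15 of them in both, where independent lists would share 9.80. ATG41-RPL36B, CIS3-FAR1, SYG1-MET30, NDI1-NGL3, LPD1-SMX2, VTC3-CTF19 and CDC34-PST1 were among the 15. NPAS2 bHLH with the Cbf1 ZIP shared 23 bound regions with Cbf1 (1.89 by independence, exact p 1.35e-20) and 22 with Cbf1 bHLH-ZIP (0.994, exact p 1.01e-25).

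The basic region of Tye7 was placed into Cbf1 bHLH-ZIP to ask whether the residues that touch DNA set the difference between the factors. Phosphate genes stood out among the losses. VTC4-RPC17 held 0 insertions against 26 (at least 7.81-fold lower) and GPI19-THI74 0 against 21 (at least 6.31-fold). CDC34-PST1 (chromosome 4, 562326 to 563526) was lower by a factor of 18.9 (7.12 to 71.1; exact test, adjusted p 5.13e-17). VTC3-CTF19 held 1 insertion against 23 (20.7, 3.36 to 854), MET17-ACO1 1 against 22 (19.8, 3.20 to 818) and SPL2-ARO9, next to a gene of phosphate homeostasis, 3 against 38 (11.4, 3.62 to 57.8). ACS1-FLC2 was lower by a factor of 7.21, NDI1-NGL3 by 6.97, MET18-STH1 by 5.06 and CIS3-FAR1 by 4.72. MET17 is deleted in BY4741, the strain of Cbf1 bHLH-ZIP, whereas the basic-region library came from BY4742 by label.

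Among the gains, HXT13-HPA3, upstream of a hexose transporter, held 28 insertions against 0, at least 10.4-fold higher. SUP45-ADH5 held 20 against 3 (7.40, 2.19 to 38.9). PFK26-MOB1, upstream of a 6-phosphofructo-2-kinase, was 5.12-fold higher, JLP1-YCT1, next to a cysteine transporter gene, 3.11-fold, MNN4-PTK1 2.54-fold, SNC2-PDR10 2.49-fold, WSC2-POP3 2.36-fold and ATP7-PUT3 2.08-fold. The last held 4.58% of the insertions, and with positions within 5 bp merged its log2 ratio turned from 1.05 to -0.06. Of the glycolytic regions that Tye7 used, TDH3-PDX1, PGI1-TAF5 and PFK2-HFA1 were not bound with the basic region. The called regions of the glycolysis list, named after their values were seen, were PEP8-TDH1, lower by a factor of 4.14, and CYC3-CDC19 (11 insertions against 2, a ratio of 6.10, 1.33 to 56.7) and PDC6-CTT1 (9 against 1, a ratio of 9.99, 1.38 to 438), both higher. The higher calls ended with scaling on regions bound in neither, and all 3 ended with positions merged or with insertions of at least 5 reads.

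Of 214 regions tested, 19 were higher and 28 lower. Scaling on regions bound in neither gave 9 and 54 (14.3% higher in place of 40.4%, log2 shift -0.40), which kept 4 of the 8 named higher and all 10 named lower regions. With positions within 5 bp merged, 1 and 5 remained past the test, with 1 of the 8 named higher and 4 of the 10 named lower regions, insertions of at least 5 reads left 8 and 18, and no minimum 9 and 20. The glycolysis list took 4.62% and 4.90% with 2 regions higher and 1 lower, the same adjusted over the list alone, at percentile 13.7. The sulfate list took 21.1% and 21.2% with 0 higher and 4 lower by either adjustment, at percentile 35.1, its pooled ratio of 0.997 turning to a log2 ratio of 0.06 outside the 10 fullest regions and to -0.41 on regions bound in neither (adjusted exact p 1.56e-09). On those regions the pooled log2 ratio of the glycolysis list moved from -0.08 to -0.49 (adjusted exact p 4.6e-05). The phosphate regulon list took 0.456% (0.314 to 0.640) and 2.38% (2.06 to 2.74), with 0 higher and 4 lower by either adjustment and a median log2 ratio of -1.85 at percentile 0.01.

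Cbf1 is also a centromere protein, so regions that span a centromere were read separately. The 16 such regions took 1.28% of the Cbf1 insertions (1.15 to 1.42) against 1.27% of the background (exact p 0.923). The region of MET14 alone held 169 of the 348 insertions, and without it the share was 0.660% (0.567 to 0.763) where the background held 1.22% (1.14 to 1.30). With the Tye7 basic region the share was 1.77% (1.48 to 2.10; exact test, adjusted p 0.00113), or 1.13% (0.903 to 1.41) without the MET14 region. Cbf1 bHLH-ZIP held 1.32%, or 0.797% without the MET14 region, and Cst6 held 0.180% where its background held 1.54%. Bound regions took 67.8% of the intergenic insertions of Cbf1 and 71.4% of those of Cst6, which lowers the shares of all other regions. The centromere shares were not rescaled for this, so a share at or below the background does not show an absence of binding.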

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

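The readings in this part were made after the data were seen, and none of the differences in it was tested as such. PUT4-CIN1, upstream of a proline permease, stood out because the ZIP went with opposite directions in the Cbf1 and NPAS2 pairs. In Cbf1 its log2 ratio with the ZIP over without was -2.68, from 1 insertion against 40, lower by a factor of 12.5 (2.12 to 506). In NPAS2 it was 1.41, from 21 insertions against 6, higher by a factor of 2.96 (1.15 to 8.95). The Cbf1 call is 1 of the 70 regions higher without the ZIP. Scaling on regions bound in neither library kept 0 of those 70 calls, so this call ended. Merging positions within 5 bp kept 1 of the 70, and insertions of at least 5 reads kept 3. The difference between the pairs was not tested, and no explanation was tested.

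Insertions outside the intergenic regions, which the comparisons did not use, were counted in windows of 500 bp, and windows that were the fullest of a library are given here as shares of all insertions of a library. On chromosome 7 at 271500 to 271999, between the regions SOH1-SCS3 and SCS3-MET13, the share was 7.61% in NPAS2 bHLH-Cbf1 ZIP, 5.60% in Cbf1 bHLH-ZIP, 3.02% in Cbf1 and 1.94% in the Tye7 basic-region library. The same window held 0.549% in Cbf1 bHLH, 0.509% in NPAS2 bHLH, 0.128% in Gcr1, 0.124% in Gcr2 and 6 insertions in Tye7. On chromosome 12 at 651000 to 651499, between NDL1-HAP1 and GSY2-HSP60, Gcr1 held 1.10%, TEF1p-Tye7 0.847%, Gcr2 0.434%, TEF1p-Tye7 gcr2D 0.350% and Tye7 0.333%, against 2 insertions in Cbf1. On chromosome 15 at 215500 to 215999, between PRS5-MAM3 and MAM3-GPD2, Cst6 held 1.39% and Gcr1 2 insertions. On chromosome 16 at 855500 to 855999, between NCA2-TPO3 and KRE6-GPH1, the share was 1.46% in TEF1p-Tye7 and 1.79% in TEF1p-Tye7 gcr2D, with 0.821% in Tye7, 0.243% in Gcr1, 0.181% in Gcr2 and 0 insertions in Cbf1. There the Tye7 basic-region library held 37 insertions (0.397%) and Cbf1 bHLH-ZIP 1. Because these positions lie outside the listed regions, the region counts of the report do not include them.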

How the results depend on the processing

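Alternatives chosen after the data were seen were scaling on regions bound in neither library, all scalings of gene lists, runs not overlapping, leaving out or keeping single runs, the other background set, the arm rule for centromeres and leaving out the MET14 region. The others were chosen before. For short, the comparisons are Tye7 over Cbf1, shortening (Cbf1 bHLH-ZIP over Cbf1), ZIP loss (Cbf1 bHLH over Cbf1 bHLH-ZIP), the basic region (Tye7 basic over Cbf1 bHLH-ZIP), ZIP gain (NPAS2), GCR2 loss (gcr2D over TEF1p-Tye7) and the TEF1 promoter (TEF1p-Tye7 over Tye7). Where the way a setting is built does not show the cause of a change, the cause was not tested. No paired analysis was possible because each group has 1 library.

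Counts of called regions stayed within 1.5 times of the reported count in 89 settings and moved further in 55, and bound counts did so in 74 and 13. Log2 ratios of named regions kept their side and their call in 955 settings, lost the call in 168 and turned in 4. Pooled list ratios kept side and call in 153, turned in 55, lost the call in 35 and gained it in 9. Of the 55 turned list ratios, 13 passed the exact test on both sides, 13 with the reported setting alone, 9 with the alternative alone and 20 with neither. A pseudocount of 0.5 and leaving out regions at deleted or plasmid-borne genes and chromosome ends left each count of called regions within 1.5 times. So did the other background set for bound regions. Leaving out deleted or plasmid-borne genes and chromosome ends removed GPI2-GCR1, MNT2-ADH4 (chromosome 7, 14157 to 15159) and other named regions. For GCR2 loss it left 7 of 10 named higher and 8 of 10 named lower regions. For the basic region it left 6 of 8 and 9 of 10, and for the TEF1 promoter 6 of 8 higher. It left 9 of 10 named higher regions each for Tye7 over Cbf1, ZIP loss and ZIP gain. That setting therefore gives no check of the regions it removed.

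Keeping insertions of at least 5 reads moved higher regions from 205 to 134 (Tye7 over Cbf1), 6 to 3 (shortening), 70 to 3 (ZIP loss), 19 to 8 (the basic region), 37 to 12 (ZIP gain) and 32 to 18 (GCR2 loss), and lower regions from 7 to 4 (shortening), 28 to 18 (the basic region) and 3 to 0 (ZIP gain). This setting removes insertions, so fewer regions could be tested. Testing with no minimum of insertions moved higher regions from 70 to 19 (ZIP loss), 19 to 9 (the basic region) and 32 to 15 (GCR2 loss), and lower regions from 7 to 1 (shortening) and 3 to 1 (ZIP gain). More tests raise the adjusted p by construction. A ratio of 4 moved higher regions from 205 to 112 (Tye7 over Cbf1), 6 to 1 (shortening), 19 to 12 (the basic region) and 9 to 3 (the TEF1 promoter), and lower regions from 7 to 2 (shortening) and 28 to 14 (the basic region). A stricter ratio can only lower counts. Thinning the deeper library moved higher regions from 205 to 120 (Tye7 over Cbf1) and 70 to 43 (ZIP loss), and lower regions from 7 to 3 (shortening).

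Merging positions within 5 bp moved higher regions from 205 to 27 (Tye7 over Cbf1), 6 to 14 (shortening), 70 to 1 (ZIP loss), 19 to 1 (the basic region), 32 to 0 (GCR2 loss) and 9 to 14 (the TEF1 promoter), and lower regions from 151 to 91 (Tye7 over Cbf1), 7 to 0 (shortening), 28 to 5 (the basic region), 3 to 1 (ZIP gain) and 3 to 0 (the TEF1 promoter). Merging lowers dense regions by construction. It also turned the log2 ratios of MAK21-LCB2 (-1.43 to 0.16) and SET2-ERG20 (-1.89 to 0.019) for shortening, ATP7-PUT3 (1.05 to -0.058) for the basic region and ADH1-PHM7 (-2.02 to 0.31) for the TEF1 promoter.

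Leaving the 10 fullest regions of each library out of the scaling moved higher regions from 70 to 8 (ZIP loss), 32 to 11 (GCR2 loss) and 9 to 22 (the TEF1 promoter), and lower regions from 7 to 1 (shortening), 3 to 1 (ZIP gain) and 3 to 1 (the TEF1 promoter). Pooled log2 ratios of lists turned as well. For Tye7 over Cbf1, phosphate went from 0.065 to -0.042. For shortening, retrograde went from -0.15 to 0.051. For the basic region, sulfate went from -0.0044 to 0.056. For ZIP gain, glycolysis went from -0.20 to 0.90 and retrograde -0.69 to 0.41. For GCR2 loss, phospholipid went from 0.29 to -0.24 and ribosomal protein 0.46 to -0.071. For the TEF1 promoter, respiratory chain went from -0.52 to 0.0039 and galactose -0.48 to 0.051.

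Scaling on regions bound in neither library moved higher regions from 205 to 31 (Tye7 over Cbf1), 6 to 12 (shortening), 70 to 0 (ZIP loss), 19 to 9 (the basic region), 32 to 9 (GCR2 loss) and 9 to 28 (the TEF1 promoter), and lower regions from 7 to 0 (shortening), 57 to 134 (ZIP loss), 28 to 54 (the basic region), 3 to 0 (ZIP gain) and 3 to 1 (the TEF1 promoter). Pooled log2 ratios of lists changed under it too. For Tye7 over Cbf1, phosphate went from 0.065 to -1.11, phospholipid 0.98 to -0.19 and ribosomal protein 0.67 to -0.51. For shortening, phosphate went from -0.35 to 0.013, phospholipid -0.22 to 0.15, retrograde -0.15 to 0.22, galactose -0.28 to 0.093 and ribosomal protein -0.28 to 0.090. For ZIP loss, ribosomal protein went from 1.24 to -0.28, phospholipid 1.55 to 0.027 (adjusted exact p 0.888) and galactose 1.77 to 0.25 (adjusted exact p 0.621). For the basic region, glycolysis went from -0.084 to -0.49 (adjusted exact p 4.6e-05), sulfate -0.0044 to -0.41 (adjusted exact p 1.56e-09), respiratory chain 0.34 to -0.068 and phospholipid 0.34 to -0.061. For ZIP gain, glycolysis went from -0.20 to 1.89, phospholipid -1.76 to 0.33 and retrograde -0.69 to 1.40. For GCR2 loss, phospholipid went from 0.29 to -0.32, galactose 0.53 to -0.078 and ribosomal protein 0.46 to -0.15. For the TEF1 promoter, respiratory chain went from -0.52 to 0.11, galactose -0.48 to 0.15 and ribosomal protein -0.60 to 0.034.

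With regions upstream of 1 gene only, pooled log2 ratios of lists changed in these cases. For Tye7 over Cbf1, phosphate went from 0.065 to -2.88. For shortening, glycolysis went from 0.52 to 0.24 (adjusted exact p 0.551), respiratory chain 0.016 to -0.38 and phospholipid -0.22 to 0.035. For ZIP loss, glycolysis went from -1.16 to 0.72 and respiratory chain -1.40 to 0.65. For the basic region, sulfate went from -0.0044 to 0.041, respiratory chain 0.34 to -0.14, phospholipid 0.34 to -0.85, retrograde 0.43 to -0.35 and ribosomal protein -0.15 to 1.19. For ZIP gain, respiratory chain went from 0.55 to -1.24 and phosphate 0.97 to -0.24. For GCR2 loss, sulfate went from -1.44 to 1.54. For the TEF1 promoter, sulfate went from 0.57 to -1.05. Without the fullest member of a list, they changed in the cases that follow, several of them the same lists. For Tye7 over Cbf1, phosphate went from 0.065 to -2.96. For shortening, glycolysis went from 0.52 to 0.24 (adjusted exact p 0.188) and respiratory chain 0.016 to -0.28. For the basic region, glycolysis went from -0.084 to -0.47 (adjusted exact p 0.025), respiratory chain 0.34 to -1.22, phospholipid 0.34 to -0.14 and retrograde 0.43 to -0.43. For ZIP gain, respiratory chain went from 0.55 to -1.45 and phosphate 0.97 to -2.18. For GCR2 loss, sulfate went from -1.44 to 1.19, phosphate -0.71 to 0.89 and deletion loci -1.93 to 1.27. For the TEF1 promoter, sulfate went from 0.57 to -0.67 and deletion loci 1.51 to -0.91. The former setting drops divergent regions such as TDH2-MET3, ADH1-PHM7 and IDH1-NCE103.

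Requiring that runs do not overlap left 68 higher regions for Tye7 over Cbf1 in place of 205. Without run 3 of Cbf1 bHLH, 25 regions were higher after ZIP loss in place of 70. That run held 20443 of the 25688 intergenic insertions, so 216 regions could be tested in place of 807. With run 2 of TEF1p-Tye7 alone, 9 regions were higher after GCR2 loss in place of 32, and 0 in place of 3 were lower with the TEF1 promoter. Run 2 held 2670 of the 7609 intergenic insertions, so depth fell here too. After GCR2 loss, 182 regions could be tested in place of 270. With runs 3 and 4 of Gcr1 and run 1 of Gcr2, these factors shared 29 bound regions in place of 51. Those runs gave 46 bound regions in place of 64 for Gcr1 and 59 in place of 79 for Gcr2, so depth fell as well. Without the MET14 region, centromere-bearing regions took 0.660% in place of 1.28% of Cbf1 and 0.797% in place of 1.32% of Cbf1 bHLH-ZIP.

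Thinned to the depth of the shallowest library, bound regions fell to 64 from 177 for Cbf1, 38 from 64 for Gcr1, 26 from 79 for Gcr2, 54 from 162 for Cst6, 18 from 44 for TEF1p-Tye7 gcr2D, 43 from 76 for the basic-region library, 51 from 93 for Cbf1 bHLH-ZIP and 11 from 99 for Cbf1 bHLH. Numbers of bound regions of these 8 libraries therefore depend on depth. With an adjusted p under 0.0001, TEF1p-Tye7 gcr2D had 29 bound regions in place of 44, and Gcr2 shared 7 in place of 12 with Cst6 and 5 in place of 9 with Cbf1. With the hypergeometric p-value, Cbf1 bHLH had 65 in place of 99.

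In simulated data at the depth of each pair, 2-fold changes were recovered in 11.9% of regions for ZIP loss, 16.7% for the basic region, 17.9% for Tye7 over Cbf1, 22.4% for shortening, 23.9% for the TEF1 promoter, 24.4% for GCR2 loss and 27.3% for ZIP gain. A call needs a ratio of at least 2, which itself limits recovery at a true change of 2-fold, so changes near 2-fold were mostly missed in all 7 comparisons. Changes of 4-fold were recovered in 70.0% (ZIP gain) to 94.4% (the basic region). The settings for sites of CACGTG (other distances, a read minimum, a longer site and leaving out the fullest regions) and for centromere distance were not run, because no sequence of the build was used here.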

Other observations

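The largest shares of Cst6 beyond those named in the report lay at RHO5-RPS3 (3.30%), PMA1-PMC1 (2.93%), AAC3-IST2 (2.20%), GIP3-ISU1 (2.14%), MAM3-GPD2 (2.01%), AAT1-GFA1 (1.70%, from 0.508% to 2.15% of a run) and GID8-GAT2 (1.61%). IDH1-NCE103, which led the Cbf1 library, held 3.84% of run 1 of Cst6 and 0.869% and 0.744% of its other runs.

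The tests in what follows were chosen after the data were seen. For Tye7 over Cbf1, a first test by the scaled count was replaced after its result was seen, because the scaling largely fixes that count, which is given without a verdict. Where runs of 1 library differ, the labels give no group for a run, so no biological explanation was tested for those patterns.

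ADH1-PHM7 held 0.0260% of run 1 of Gcr1 against 3.73% of its other runs, 0.0472% of run 2 of Gcr2 against 4.18%, and 0.182% of runs 1 and 3 of TEF1p-Tye7 against 1.61% of run 2. A weaker fusion in the low runs would lower the other glycolytic regions as well, but their share in low over other runs was 0.798 in Gcr1, 1.03 in Gcr2 and 0.984 in TEF1p-Tye7, which argues against that cause and leaves open another factor that uses glycolytic regions. In the low runs of Gcr1 and Gcr2, 4 of 4 insertions left lay within 125 bp (chromosome 15, 161060 to 161184), the interval that the low runs of TEF1p-Tye7 set, against 218 of 1274 (17.1%) in other runs (Fisher's exact p 0.00089). Run 1 of Cst6 (0.0706%, against 0.622% and 0.561%) and run 3 of Cbf1 bHLH (2 insertions of 20443, lower than its other runs by a factor of 23.4, interval 5.21 to 215) were low as well, with 0 of 5 and 1 of 2 insertions in that interval. Reads over most of the region may thus have been lost or filtered before deposit in the low runs of Gcr1, Gcr2 and TEF1p-Tye7, a hypothesis found and tested on the same lists, which the Cst6 insertions, at 162022 to 162105, did not follow.

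A set of 7 regions, FCF1-YDR341C, AAD15-BDS1, YPS7-ATP22, INO4-WSC3, SPO13-MIP6, HSP104-SSA2 and ICE2-AVT7, took 5.65% of runs 1 and 2 of Gcr1 against 0.252% of its other runs, and 2.41% of runs 2 and 3 of Gcr2 against 0.279% of run 1. Insertions mixed in from another library of the series would need these regions to be high there, but the highest of the other 10 libraries, TEF1p-Tye7, held 0.499%. A transfer between Gcr1 and Gcr2 was not tested. A mixture with insertions not directed by the factor would lower the glycolytic share, leaving out ADH1-PHM7. In Gcr2 that share was 8.89 points higher in the high runs. It was 25.5% and 34.6% in those runs and 20.8% in run 1. This spread exceeds the share the 7 regions gained, so the value cannot decide on a mixture. In Gcr1 the glycolytic share changed by -3.22 points, less than the share the 7 regions gained. There too a mixture and other causes cannot be told apart.

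Many regions, 205, had a higher share in Tye7 than in Cbf1 although 17 were bound in Tye7, and 68 of the 205 had runs apart. Scaled on regions bound in neither library, 31 were higher, a fall that the scaling largely fixes, since 189 of the 205 lay in the regions it rests on. Regions bound in neither library and called higher in some runs (66 and 47 in 2 splits) had, in every left-out run of Tye7, at least 2.71 times the share of any left-out run of Cbf1, which argues against spread between runs for these regions and leaves it untested for the others. Among insertions in regions bound in neither library alone, the same ratio was at least 1.12, above the 1 of a pure effect of the bound regions of Cbf1 (67.8% of its intergenic insertions) on all other shares and below the 1.5 set against it, so such an effect and other causes cannot be told apart. A difference between the factors stays open as well, as 1 library each cannot separate it from a difference between cultures.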
